A study of Homo sapiens with 2 samples.

How the data were processed

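RNA of HTB172 lung cancer cells was analysed in 2 libraries, vancomycin-treated and untreated, grouped by the treatment label with 1 library in each group. Per the labels, 10 ng of total RNA entered AmpliSeq Transcriptome libraries, and treatment lasted 48 h. Per the submitters' processing notes, the genome build was hg19 and DESeq was used, without a version. The aligner, the counting method, the strand setting and the pathway tool are not given in the sources used here.

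Per the file headers, the authors deposited a signed fold of the vancomycin against the untreated library, its log2 value and the absolute fold, a ratio of the larger to the smaller normalized value. The log2 column deposited by the authors differed from the log2 of the absolute fold by at most 2.94e-07, and no deposited fold was under 2. Per the file headers, the authors' pathway tables give a p-value per pathway with the number of listed genes and of pathway genes, with no adjustment named and 3 terms of each list entered again under the same name. The largest p-value in the authors' tables was 0.104 for the higher and 0.108 for the lower list, so the deposited terms appear selected by p. Of 12 deposited tables, 4 concern HTB172. The other 8 are named for BxPC3 and MDA cells, match no sample of the series, and their folds were not used. Their gene identifiers were read as a second background, giving 9250 identifiers over all tables, and to count identifiers shared with the HTB172 tables.

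The tables hold no level per library. The planned filter on gene level, pseudocounts, rescaling and matching of random lists on mean expression therefore had no values to work on, and the folds were used as deposited. No test between conditions was made.

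To find what a read was worth, a step was sought separately in each table. The search began at the largest step of which a set share of the folds, within a limited range, were whole multiples. Parts and multiples of that step were then compared by the share of folds they held. Folds within 0.001 of a step (or a relative 1e-06) of a whole multiple or of a fraction with a denominator that divides 12 were taken to have 1 library at a common floor. Other denominators were not tried, so folds off the multiples may still include some with a floored library. Tested on 20 simulated pairs of tables of 20000 genes each, both steps were recovered within 0.1% in 20 of 20. In the simulated higher tables, with denominators of 1 and 2 only, a median of 100% of floored genes and 0% of other genes was marked. Marking at the other denominators, and in the lower tables, was not tested. Fractions of reads occur where reads are divided among several places. In the higher and lower tables, 16.7% and 12.9% of the folds off the multiples equalled the ratio of the steps times a ratio of small read numbers, against at most 1.11% and 3.00% at 20 shifted ratios. The remaining folds off the multiples could not be resolved into reads, so that a library above the floor is inferred for them, not shown. A floored vancomycin library was given 3 reads as its upper limit. A floored untreated library, which could hold up to 2 reads, was given 6.30 reads, the one-sided upper 95% Poisson limit for 2 reads. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

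Genes were matched by Ensembl ID to GENCODE 29, which is on another build than the deposited tables, for gene type, exon number and overlap only, and no coordinates are given. Of 1753 identifiers, 1674 (95.5%) matched. Clustered histone genes were left out of the family shares because 10 of their 22 listed identifiers had no match. Exact Clopper-Pearson 95% intervals were computed with SciPy 1.17.1, with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.

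Before the data were examined, 34 gene lists, the alternatives and the rule for named genes were fixed. The rule took the 10 greatest folds in each direction, passing over uncharacterised loci and those named as antisense or open reading frames (2 in each direction), and up to 4 members with the largest absolute log2 fold from each list with 3 or more listed members. Its part on the highest mean level could not be applied without levels. Members of shorter lists were named as values, except 1 that is not reported here. The median log2 fold and the share of lower genes of each list were set against 10000 random lists of the same size from the listed genes, as a description of these libraries. Alternatives were a 4-fold threshold, random lists from all tables and, for pathways, Benjamini-Hochberg adjustment over the deposited terms at 0.05. Restriction to folds off the multiples, folds against 3 reads or against the limits above, and coding genes with 2 or more exons were chosen after seeing the data.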

Results

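RNA of the lung cancer cell line HTB172 was profiled with AmpliSeq Transcriptome, an assay that amplifies a short target from each gene's cDNA and counts the sequenced copies. There were 2 libraries, 1 from cells exposed to vancomycin and 1 from untreated cells, with a treatment time of 48 h. Vancomycin is a glycopeptide antibiotic that blocks cell wall synthesis in bacteria. The design asks which transcripts differ between treated and untreated cells. With 1 library per group there is no replicate error, so no p-value, SD or interval between conditions could be formed, and each difference describes these 2 libraries. The tables give folds of 2 or more and no level per library, so total reads per library are unknown, and a gene in neither table may be unchanged or undetected.

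The authors' deposited table for the comparison listed 275 genes higher and 1478 lower in the vancomycin library, so that 84.3% of the 1753 listed genes were lower. The lower genes with the most extreme values included MFN1, a GTPase of mitochondrial outer membrane fusion, listed 1469-fold lower in the authors' deposited table, and SLC43A2, a transporter of large neutral amino acids, listed 284-fold lower there. In the same authors' deposited table the stress-responsive kinase PLK3 was listed 52.9-fold higher and the glucose transporter gene SLC2A1 58.1-fold lower. Genes with olfactory receptor symbols, pseudogenes included, made up 29 of the higher and 165 of the lower genes. The coding members of this family encode odorant receptors of the nasal epithelium. In the authors' deposited table the median absolute fold was 6.17 among higher genes and 7.45 among lower genes, and 91 and 590 genes respectively stood at 10-fold or more.

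Many folds rested on a library with no usable signal. Folds in the higher table fell on whole multiples of 1.39, and those in the lower table on whole multiples of 0.392, for 45.1% and 44.9% of genes at a tolerance of 0.001 of a step. Counting simple fractions of a step with denominators that divide 12, the shares were 67.3% (185 genes) and 70.7% (1045 genes), against at most 4.73% and 4.67% at 50 shifted step sizes. Such folds arise when one library is set to a common lowest value and the fold is the other library's reads times the worth of 1 read. On that reading, 1 read was worth 3.54 times as much in the vancomycin library as in the untreated library, and the untreated library was the deeper one as far as the authors' scaling follows depth. The floor was then worth 2.55 untreated reads, so that a floored untreated library could hold up to 2 reads, and 0.721 vancomycin reads, so that a floored vancomycin library held no whole read. For these genes a fold is given below as "at least", set against 6.30 reads in a floored untreated library, the upper 95% limit for 2 reads, or 3 reads in a floored vancomycin library. It takes the reads of the other library as exact and covers no difference between cultures.

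**Figure D1:**
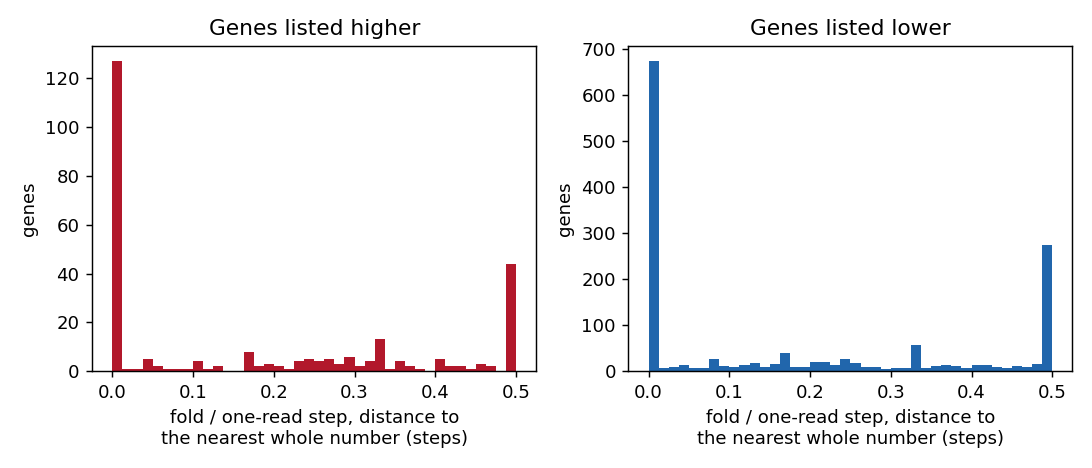
Number of genes (y axis) by the distance of fold divided by the one-read step from the nearest whole number, in steps (x axis), for the 275 genes listed higher and the 1478 listed lower. The tallest bars are at 0, where 45.1% of the higher and 44.9% of the lower folds lie within 0.001 of a whole number, and the bars at the right edge hold folds midway between whole numbers.

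Among the 10 named genes with the greatest folds listed higher, BTBD19 and PLK3 had folds off the multiples, as 2 libraries above the floor would give. BTBD19, a BTB domain gene (ENSG00000222009), was listed 285-fold higher in the authors' deposited table, which corresponds to 206 or more reads in the vancomycin library. For PLK3 (ENSG00000173846) the corresponding minimum was 38.2 reads. The other 8 were UBQLNL, OR4D9, TCFL5, OR1E2, OR4N5, OR4L1, MAPK14 and EIF1B, each with the untreated library at the floor. The rule passed over 2 loci with folds in this range, among them NCBP2-AS2, a coding gene named as antisense, at 79.0-fold higher in the authors' deposited table. Against the floor's upper limit, the folds of the authors' deposited table became at least 40.2-fold higher for the ubiquilin-like gene UBQLNL and at least 30.5-fold higher for TCFL5, a helix-loop-helix transcription factor of the male germ line. On the same basis the authors' deposited table gave at least 23.03-fold higher for MAPK14, the p38 alpha stress kinase, and at least 20.8-fold higher for EIF1B, a relative of a translation start-site factor. The olfactory receptor genes OR4D9, OR1E2, OR4N5 and OR4L1 stood between at least 23.03-fold and at least 34.3-fold higher from the authors' deposited table.

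Among the 10 named genes with the greatest folds listed lower, MFN1 (ENSG00000171109), SLC43A2 (ENSG00000167703), UIMC1, CD151 and CDC27 had folds off the multiples. The fold of MFN1 corresponds to 3749 or more reads in the untreated library, where the vancomycin library would have had 1060 at equal abundance. In the authors' deposited table UIMC1, a ubiquitin-binding partner of BRCA1 at DNA breaks, was listed 270-fold lower, and CD151, a tetraspanin that binds laminin-receptor integrins, 236-fold lower. The fold of UIMC1 came to 687.778 steps, close to a simple fraction with a denominator that was not tried. If its vancomycin library was at the floor, UIMC1 would be at least 64.8-fold lower. CDC27, a subunit of the anaphase-promoting complex, was listed 143-fold lower in the authors' deposited table. Its fold came to 364 steps, a whole number that it missed by slightly more than the tolerance, so it lay close to the folds with a floored library. If its vancomycin library was at the floor, CDC27 would be at least 34.3-fold lower. The remaining 5 were RPL29P19, DDI1, OR1L4, UBQLN2 and OR1A2, single-exon genes with the vancomycin library at the floor. From the authors' deposited table the ribosomal protein pseudogene RPL29P19 was at least 29.1-fold lower and UBQLN2, a shuttle factor that carries ubiquitinated proteins to the proteasome, at least 27.3-fold lower. Whether the reads of RPL29P19 were shared with the ribosomal protein gene it copies was not tested. DDI1, a retroviral-protease-like gene, was at least 28.7-fold lower by the authors' deposited table, and the receptors OR1L4 and OR1A2 at least 27.4-fold and at least 25.0-fold lower.

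**Figure D2:**
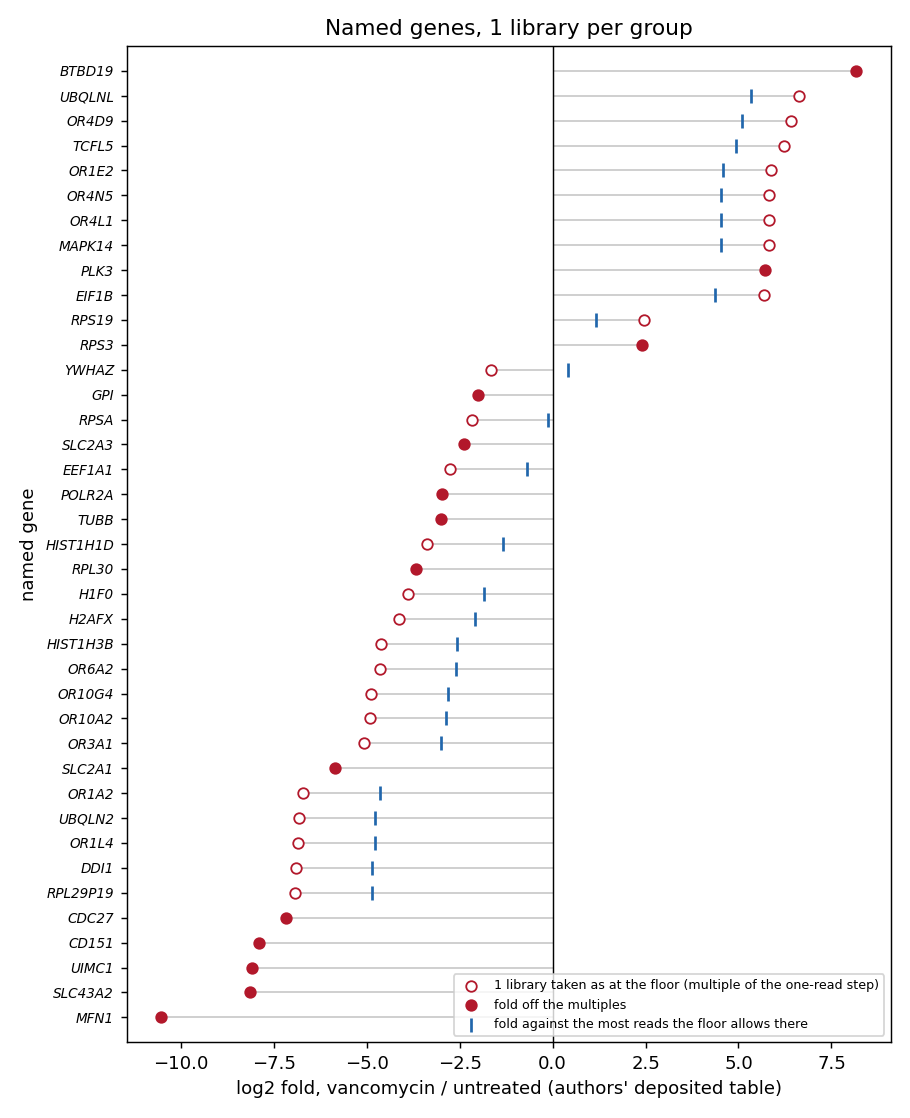
log2 fold of the vancomycin over the untreated library (x axis) from the authors' deposited table for the named genes (y axis), with filled circles for folds off the multiples, open circles for folds with 1 library taken as at the floor, and blue ticks for the fold against the most reads the floor allows in that library. MFN1 lies at -10.52 and BTBD19 at 8.15, and the tick of YWHAZ lies on the other side of 0 from its circle.

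The fixed gene lists touched few listed genes. Of 904 genes on 34 lists, 9 were listed higher and 43 lower, and 13 lists had no member in either table. Those 13 were G2/M and mitosis, apoptosis regulators, the unfolded protein and integrated stress response, heat shock proteins, cholesterol and fatty acid synthesis, NF-kappaB and inflammatory cytokines, collagens and matrix, drug transporters and xenobiotic enzymes, proteasome subunits, metallothioneins, airway and alveolar markers, pancreatic and breast carcinoma line markers, and cancer-testis antigens. Only 5 lists had 3 or more listed members.

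All 3 listed members of the glycolysis and hypoxia list were lower, and each had a fold off the multiples. In the authors' deposited table SLC2A1 stood at a log2 fold of -5.86, the neuronal-type glucose transporter gene SLC2A3 at -2.39 and GPI, which interconverts glucose and fructose phosphates, at -1.99. The minimum was 148 untreated reads for SLC2A1, but only 13.4 for SLC2A3 and 10.2 for GPI. The counting error of these folds is unknown. The other 27 members, among them HK2 and LDHA, were in neither table. The list's median of -2.39 lay at percentile 54.9 of 10000 random lists of the same size drawn from the listed genes, and its share of lower genes at percentile 69.9.

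Cytosolic ribosomal protein genes went both ways, with 2 of 4 listed members higher and 2 lower and 33 in neither table. In the authors' deposited table the log2 fold of RPS3 was 2.41, equal to that of SNORD15A, a small nucleolar RNA gene that overlaps it, and that of RPL30 was -3.67. For RPS3 the minimum was 3.83 vancomycin reads and for RPL30 32.5 untreated reads, so their counting error is unknown. RPS19 rested on 4 vancomycin reads and RPSA on 11.5 untreated reads, and with the counting error of those reads a difference was not detectable at this depth for either gene. RPSA overlaps SNORA6, which was also listed. The list's median was 0.12, or 0.53 with floored members at their bounds, and lay at percentile 95.3 of the random lists, and the share of lower genes at percentile 6.67. Processed pseudogene copies of ribosomal protein genes are common, and whether reads were shared with them was not tested, so the single folds are uncertain.

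Of the core histone list, 6 members were listed lower, 1 higher and 18 in neither table. All 6 members listed lower had the vancomycin library at the floor. For HIST1H2AG, on 12.3 untreated reads, a difference was not detectable at this depth with the counting error of those reads. From the authors' deposited table HIST1H3B was at least 5.89-fold lower, H2AFX, whose product is phosphorylated at DNA breaks, at least 4.24-fold, the linker histone gene H1F0 at least 3.58-fold and HIST1H1D at least 2.50-fold. The higher member, HIST1H3D, had a log2 fold of 1.37 in the authors' deposited table, with a minimum of 1.87 vancomycin reads. The list's median was -3.38, or -1.32 at the bounds, at percentile 15.4 of the random lists, and the share of lower genes lay at percentile 50.1. HIST1H3B, HIST1H1D and HIST1H3D belong to clusters of similar genes, and sharing of reads between them was not tested. The fold of HIST1H3D matched that of HIST1H2AD, at 2.59227 for both and off the multiples. These 2 values may therefore rest on the same reads, which was not tested.

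Of the olfactory and taste receptor genes on the fixed list, 8 members were listed lower, 2 higher and 21 in neither table. OR7C1 and OR8D1 rested on 10 and 14.5 untreated reads. With the counting error of those reads a difference was not detectable at this depth for either gene. From the authors' deposited table OR3A1 was at least 8.06-fold lower, OR10A2 at least 7.26-fold, OR10G4 at least 7.05-fold and OR6A2 at least 6.03-fold, all with the vancomycin library at the floor. OR3A1 overlaps OR3A2, which was also listed. The list's median log2 fold of -3.37, or -1.31 at the bounds, lay at percentile 11.1, and its share of lower genes at percentile 33.5.

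Of the housekeeping list, 4 members were listed lower and 23 were in neither table. In the authors' deposited table TUBB, a beta-tubulin gene, stood at a log2 fold of -3.01 and POLR2A, the catalytic subunit of RNA polymerase II, at -2.98. The minimum was 20.6 untreated reads for TUBB and 20.2 for POLR2A, so their counting error is unknown. EEF1A1, the translation elongation factor, was at least 1.62-fold lower by the authors' deposited table. YWHAZ had 8 untreated reads, for which 2.26 vancomycin reads were expected, so a difference was not detectable at this depth. The list's median was -2.87, or -1.84 at the bounds, at percentile 38.2, and its share of lower genes lay at percentile 75.0.

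For lists with 1 or 2 listed members, single values are given. The log2 folds here are off the multiples, so their reads are known only as a minimum and their counting error is unknown. This minimum ran from 5.21 untreated reads for JAG2 to 104 for LYZ, with 6.04 for DLL3, 6.57 for SOD2, 7.29 for AKT2 and 8.75 for DLG4. For the higher genes FTH1 and CLDN3 it was 6.09 and 6.22 vancomycin reads. In the authors' deposited table the G1/S transcription factor gene E2F1 stood at a log2 fold of -4.31, and MSH6 of mismatch repair at -2.77. The complex I subunits NDUFS3 and NDUFV2 stood at -4.01 and -2.41 in the authors' deposited table, and the mitochondrial ribosomal genes MRPL4 and MRPL51 at -1.81 and -1.80. Of the neuroendocrine list, INSM1, a zinc finger factor of endocrine progenitors, was at least 4.15-fold lower and the Notch ligand DLL3 had a log2 fold of -1.24 by the authors' deposited table. Signalling genes in the authors' deposited table were CTNNB1 at -2.95, JAG2 at -1.03 and AKT2 at -1.52, with the synaptic scaffold gene DLG4 at -1.78. On the oxidative stress list FTH1, the ferritin heavy chain, stood at 3.08 and SOD2 at -1.36 in the authors' deposited table, and the tight junction gene CLDN3 at 3.11. Of the immediate early genes, JUND, on 5.5 vancomycin reads, was at least 3.09-fold higher and IER3 at least 1.84-fold lower by the authors' deposited table. IFI35, the single interferon-stimulated member, was at least 2.36-fold lower by the authors' deposited table, and LAMP1 had 9 untreated reads, too few to show a difference. Markers of other cell types also appeared, with LYZ at -5.36, CD14 at -4.32 and PDGFRA at -2.36 in the authors' deposited table, beside 2 of 19 leukocyte and 1 of 18 fibroblast and endothelial list genes listed.

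By annotation, protein-coding genes were 64.4% of the higher and 64.9% of the lower table, and processed pseudogenes 37 and 225 genes. Genes with a single exon were 46 of 177 higher coding genes (26.0%, exact 95% interval 19.7 to 33.1) and 279 of 959 lower ones (29.1%, 26.2 to 32.1), against 4.91% of 19951 annotated coding genes. Without olfactory and taste receptors, keratin-associated proteins and histones, the shares were 22.4% and 21.5%, against 3.24%. Of 386 annotated coding olfactory receptor genes, 164 were listed (42.5%, 37.5 to 47.6), as were 40 of 94 keratin-associated protein genes (42.6%, 32.4 to 53.2), which encode hair shaft proteins. Zinc finger genes named ZNF were listed in 43 of 514 cases (8.37%, 6.12 to 11.1). Of the 194 listed olfactory receptor symbols, 94.3% had 1 library at the floor, and 85.1% were lower (79.2 to 89.8), against 84.2% of the other listed genes (82.3 to 86.0). These binomial intervals cover counting of genes only.

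**Figure D3:**
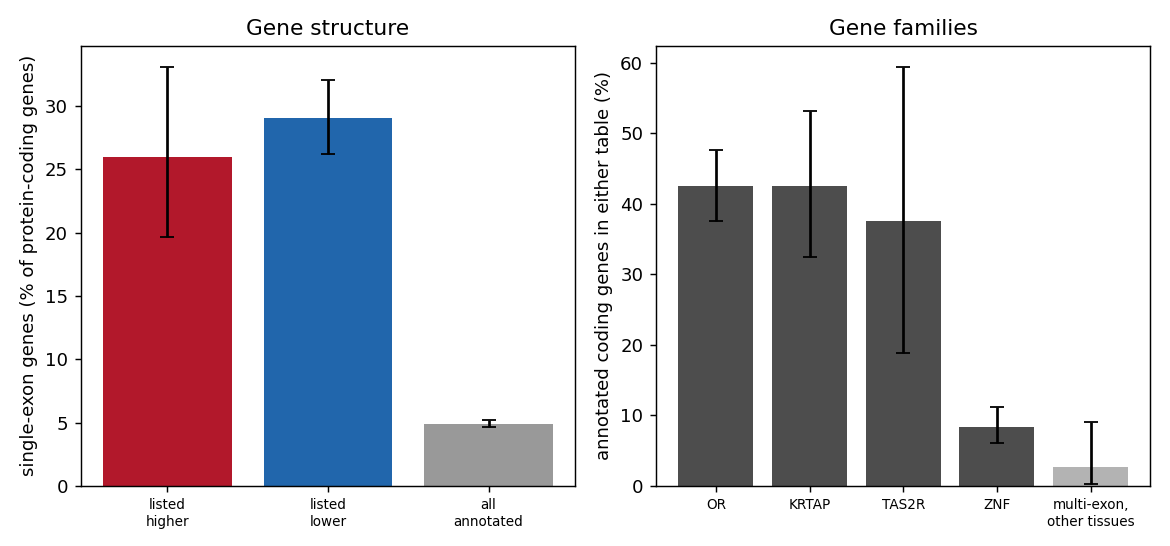
Left, percent of protein-coding genes that have a single exon (y axis) among genes listed higher, listed lower and in the whole annotation. Right, percent of annotated coding genes found in either table (y axis) for 4 families and for multi-exon genes typical of other tissues. Bars are shares and lines exact 95% binomial intervals, with 26.0% and 29.1% single-exon genes among listed genes against 4.91% in the annotation, and 42.5% of olfactory receptor genes listed.

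The pathway tables addressed which annotated processes the listed genes belong to. For the higher list, the authors' deposited table led with Eukaryotic Translation Termination, with 5 of 88 genes and a p-value of 5.37e-05, followed by Nonsense-Mediated Decay with 5 of 111 genes and a p-value of 0.000162. The EGF-EGFR Signaling Pathway had 5 of 162 genes and a p-value of 0.00109 in the authors' deposited table. For the lower list, the authors' deposited table led with GPCRs, Class A Rhodopsin-like, with 38 of 262 genes and a p-value printed as 0. Histone Modifications followed with 16 of 67 genes and a p-value of 7.26e-10 in the authors' deposited table, and Glycolysis and Gluconeogenesis had 6 of 49 genes and a p-value of 0.00152. Several terms stood in both lists, including Eukaryotic Translation Termination, with 6 of 88 lower genes and a p-value of 0.0209 in the authors' deposited table. Nonsense-Mediated Decay in the authors' deposited table also had 9 of 111 lower genes with a p-value of 0.00164, GPCRs, Class A Rhodopsin-like 6 of 262 higher genes with a p-value of 0.00145, and Histone Modifications 2 of 67 higher genes with a p-value of 0.0408. These p-values take the gene lists as given and carry no replicate error. Single-exon genes were in excess in both lists, at 26.0% of higher and 29.1% of lower coding genes against 4.91% of annotated ones. Whether that excess contributed to these terms, among them the receptor and histone terms, was not tested.

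Restricting the tables to folds off the multiples left 90 higher and 433 lower genes, and restricting them to coding genes with several exons left 131 and 680. At 4-fold or more, the authors' deposited table held 177 higher and 1093 lower genes.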

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

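The settings using folds off the multiples, folds against 3 reads or the floor's upper limit, and coding genes with several exons were chosen after seeing the data. More genes were lower than higher under each setting run, with 5.37 lower genes per higher gene as deposited, 6.18 at 4-fold or more, 4.81 off the multiples, 5.19 among coding genes with several exons, 3.81 against 3 reads and 4.72 against the floor's upper limit. Of the alternative values, 22 stayed close to the main value, within 1.5 times for a count or ratio and within the 95% interval of 10000 random lists for a percentile, and 23 moved. Counts of genes moved because the settings keep fewer genes, and the pathway counts through the adjustment. For the percentiles the cause was not tested, except as stated below. At 4-fold or more, the higher genes numbered 177, the higher core histone members 0, and the percentile of the median was 24.9 for core histones, 9.72 for olfactory and taste receptors and 59.6 for housekeeping genes. Off the multiples, there were 90 higher and 433 lower genes and 14 of 39 named genes, with CDC27 and UIMC1 counted among the 14. Listed lower under that setting were 1 ribosomal, 0 histone, 0 olfactory and taste receptor and 2 housekeeping members, and listed higher were 1 ribosomal and 1 olfactory and taste receptor member. Among coding genes with several exons there were 131 higher and 680 lower genes. With random lists from all tables, the percentile of the share listed lower was 8.44 for ribosomal proteins, 28.5 for glycolysis and hypoxia, 98.1 for core histones, 98.9 for olfactory and taste receptors and 58.8 for housekeeping genes. The number of members listed in either direction stood at percentile 98.8 for core histones and 99.7 for olfactory and taste receptors against that background, so these moves reflect how many members were listed, while the share of lower genes among listed ones stood at 50.1 and 33.5. Adjustment over the deposited terms left 20 of 38 pathways of the higher list and 28 of 47 of the lower list at 0.05. These counts include terms entered again and are too lenient, since the deposited terms were already limited to p-values up to 0.104 and 0.108. The filters on gene level, pseudocounts of 1 and 10, housekeeping and equal-sum rescaling, and matching on mean expression were not run, because no level per library was at hand. For the same reason neither the ratio of lower to higher genes nor the direction of a gene family was checked under another scaling. For glycolysis and hypoxia, too few members stood at 4-fold for a percentile. No replicate could be left out with 1 library per group. No paired analysis was possible because each group has 1 library and no result comes from a test. Depth limits the floored genes: 468 of 1045 floored lower genes and 61 of 185 floored higher genes were under 2-fold against the floor's upper limit.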

Other observations

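The tests of read sampling, of few molecules, of genomic DNA and of the direction of olfactory receptor genes, and the gene groups and single genes given here, were chosen after the tables were seen. By the deposited gene ontology terms, 53 of 60 listed mitochondrial genes were lower (88.3%, exact 95% interval 77.4 to 95.2), against 84.6% of all listed genes with a term. The 7 higher ones included DAP3 of the mitochondrial ribosome, and the lower ones MFN1, the mitochondrial ferritin gene FTMT and SURF1, a cytochrome oxidase assembly factor. Nucleosome genes were lower for 25 and higher for 3, and oxidation-reduction genes lower for 23 and higher for 2. Genes with the term for structural constituents of the ribosome were lower for 12, such as RPL21 and RPS18, and higher for 4. The lower ones also included ANKRD42, EXOSC2 and TRIP11, which have no ribosomal protein symbol. Among the higher ones, RPL9 rested on 6 vancomycin reads with the untreated library at the floor. Genes of the apoptotic process were lower for 22 and higher for 4, a split of 84.6% like that of all annotated genes.

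Among folds off the multiples beyond the named genes, the authors' deposited table had FADS2, a fatty acid desaturase, at a log2 fold of 3.34, the Notch coactivator MAML2 at 3.43 and TRAPPC2, a vesicle tethering gene, at 4.15. On the lower side, the authors' deposited table had the sulfotransferase SULT1B1 at -5.96, EXOC7 of the exocyst at -5.44 and the potassium channel regulator ABCC9 at -5.18. Folds off the multiples that were equal to 6 decimals occurred in 24 groups of genes. Of these, 17 were pairs with both genes matched in the annotation, and 12 of the pairs overlap there, among them RPS3 with SNORD15A and NDUFV2 with a neighbouring unnamed locus. Of the 194 listed olfactory receptor symbols, 118 (60.8%, exact 95% interval 53.6 to 67.7) were also in the tables named for BxPC3 and 33 (17.0%, 12.01 to 23.05) in those named for MDA. Among all 1753 listed genes, the receptors included, the shares were 53.7% and 12.4%. The receptors were not set against the other listed genes alone, so whether they recur more often was not tested. Over all listed genes, 942 were shared with BxPC3 and 217 with MDA, where independent lists among the 9250 identifiers would share 1576 and 90.0, but those identifiers are only the ones listed in some table.

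The first pattern weighed is the excess of lower genes. How far it depends on the authors' scaling of the 2 libraries was not checked, because no level per library was at hand. Read sampling at a lower depth of the vancomycin library is argued against as the whole cause, because 369 lower genes at the floor had 10 or more vancomycin reads expected, where independent sampling would leave about none. Few starting molecules, copied many times in libraries from 10 ng of RNA, stay open as a contributor. The untreated library was at the floor, with 2 reads or fewer, for 138 higher genes where 10 or more were expected. That count cannot decide, because it concerns higher genes and not the excess of lower ones. It also takes in genes on few reads, such as RPS19 on 4 vancomycin reads with 14.1 untreated reads expected. For RPS19 a difference was not detectable with the counting error of those reads. Real responses to vancomycin in both directions would give the same counts, and they stay open and untested because treatment and library coincide.

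In the second pattern, single-exon genes and families such as the olfactory receptors, some with a further annotated exon, recur in both tables. Of annotated olfactory receptor genes 42.5% were listed, but 2 of 77 (MYH6 and TNNC2) multi-exon genes typical of liver, muscle, eye, pancreas, kidney, blood and skin (2.60%, exact 95% interval 0.316 to 9.07), a list fixed before its test. Low expression alone would have kept the first share below 9.07% had olfactory receptor genes been as silent as the others. That silence was not measured, so low expression stays open. For counting only reads that lie within an exon, the forecast was likewise a share below 9.07%, but the comparison cannot decide. Such counting would remove reads from the multi-exon comparison genes and spare single-exon genes, so it could itself give the gap and the excess of single-exon genes. Genomic DNA amplified beside the cDNA is also a candidate explanation, with single-exon genes at 29.1% of lower coding genes against 4.91% of annotated ones, although the labels name both a column kit and a phenol-based RNA isolation and whether DNA was digested is not given in the sources used here. A direction particular to olfactory receptor genes could not be decided, as 85.1% of them were lower, with an interval of 79.2 to 89.8 that spans the 84.2% of other genes.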
